A study of Mus musculus with 8 samples.

How the data were processed

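The series measured splenic conventional dendritic cells of untreated female C57BL/6 mice, wild type or RAG2-deficient, 10 weeks old per the labels and sorted as CD8α+ or CD8α- cells. Total RNA was labelled with biotin and read on Affymetrix mouse arrays, 8 arrays in 4 groups of 2. The deposited values are log2 expression summaries per probe set, normalized by the authors. The submitters' processing notes name GCRMA and affy for the wild type arrays and GCRMA alone for the knockout arrays. Versions, the annotation used and which arrays were normalized together are not given in the sources used here. The knockout arrays share one lowest value that the wild type arrays lack, so the genotypes were evidently processed apart, and each comparison of genotypes carries that difference with it. Scanner files were not used. The labels number the replicates but do not say that they came from separate mice, so the p-values may measure technical spread. The number of arrays, not a depth, limits the precision.

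Of 45101 probe sets, 34958 carried 1 gene name, 932 several and 9160 none, and 64 were array controls. Probe sets with a log2 value of at least 5 on at least 2 of the 8 arrays were kept, and each gene was represented by its probe set with the highest mean over the 8 arrays, which left 8763 genes. Values were used as deposited. A linear model of the 4 groups was fitted with limma 3.58.1 in R 4.3.3 (plain eBayes, 4 residual degrees of freedom), with 5 comparisons: CD8α+ against CD8α- cells in each genotype, knockout against wild type in each subset, and the interaction of genotype and subset. The interaction is the knockout change in CD8α+ cells less that in CD8α- cells, so that offsets shared by all arrays of a genotype cancel. P-values were 2-sided and adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Changes in the 2 genotypes, or in the 2 subsets, were compared across genes by Pearson and Spearman correlation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

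Before the data were examined, the comparisons, the filter, the rule for naming genes, 30 gene lists with 504 genes and a set of other settings were fixed. The rule named the 12 genes with the largest rise and the 12 with the largest fall in each comparison among called genes whose arrays did not overlap between the groups, all called genes for the interaction, members of the lists, Rag1, Rag2, Cd8a and Cd4 as checks of the labels, and control probe sets as a check of RNA quality. Other genes are not named. A gene whose lower group was below log2 5 on each of its arrays is given as at least so many fold, against a level of 5. The lists covered CD8α+, CD8α-, conventional and plasmacytoid dendritic cell markers, MHC class II and class I presentation, costimulation, type I interferon-stimulated and interferon-gamma-inducible genes, NF-kB targets, Toll-like receptors, chemokine receptors, Notch and lymphotoxin genes, C-type lectins and phagocytic receptors, markers of T, B, NK, macrophage, neutrophil, erythroid, megakaryocyte, mast and stromal cells, cell cycle, immediate early, ribosomal protein, oxidative phosphorylation, cholesterol synthesis, unfolded protein response and clock genes. Each list with at least 5 tested members was tested with camera (preset correlation 0.01), adjusted over the lists of a comparison. Calls were repeated with an estimated correlation and with fry. RNA-quality controls were compared between the genotypes by an exact permutation test.

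These other settings were quantile normalization of the 8 arrays, centring each array on its median, no filter or a filter at log2 7, an offset of 16 on the linear scale, the mean of a gene's probe sets or each probe set on its own, limma-trend with robust eBayes, a fit of the compared groups alone, array weights, the replicate number as a block, a further requirement of a log2 change of 1, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other groups. Added after the data were seen were the block with numbers exchanged in one knockout group, leaving out the 2 knockout arrays with neutrophil transcripts, setting values below 5 to 5, and counting only genes whose 2 brightest probe sets both passed. The replicate numbers did not pair the arrays (r of replicate differences between groups from -0.146 to 0.112), so no pairing was used. The fit was tested on simulated data with 200 changed genes and a planted list, in which 5.37%, 4.23%, 5.48%, 8.78% and 7.41% of the calls were false in the 5 comparisons. Far more genes were called in the data between subsets or genotypes, so these rates need not carry over.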

Results

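Splenic conventional dendritic cells sorted by CD8α from wild type and RAG2-deficient mice were compared to ask how the absence of T and B lymphocytes bears on these antigen-presenting cells. Levels are log2 expression values given as the mean ± SD of the 2 arrays of a group. The sort was visible in the transcripts of the sorting markers. Cd8a, the α chain of the CD8 coreceptor, stood at 11.83 ± 0.15 in wild type CD8α+ cells and 5.95 ± 0.21 in wild type CD8α- cells, and at 12.41 ± 0.14 and 7.30 ± 0.57 in the knockout. Cd4, the other T cell coreceptor, ran the opposite way, with 2.77 ± 0.01 and 7.95 ± 0.18 in wild type and 4.11 ± 0.05 and 10.62 ± 0.87 in the knockout. Rag1 and Rag2 were below log2 5 on all 8 arrays and so carried no information on the genotype. The antibody transcripts Igha and Igkv8-30 were present in both wild type groups, at 8.99 to 10.09, and below 5 on each knockout array. The first principal component held 47.4% of the variance and separated the subsets within each genotype. The second held 38.7% and separated the genotypes. Replicates correlated across genes at r = 0.987 and 0.982 in wild type CD8α- and CD8α+ cells, and at 0.969 and 0.975 in the knockout, where genes are not independent replicates.

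In wild type cells, many genes named for a large difference between the subsets were near background in one subset and abundant in the other. Mab21l3, a nucleotidyltransferase-fold gene, stood at 10.56 ± 0.15 in CD8α+ cells and 2.31 ± 0.03 in CD8α- cells, at least 47.0-fold higher (limma, adjusted p = 2.26e-06). P3h2, a collagen prolyl hydroxylase, was at least 63.5-fold higher (0.00112), the adhesion gene Hepacam2 at least 29.4-fold (9.71e-05), the amino acid transport regulator Cltrn at least 23.2-fold (4.00e-05), Ttc39a at least 47.6-fold (0.000277), Gm36723 at least 28.6-fold (0.000547) and Fam149a at least 19.8-fold (7.11e-05). Ptgis, which makes prostacyclin, was at least 13.3-fold higher and the integrin gene Itga8 at least 15.1-fold. The lipid phosphatase gene Plpp1 rose by 6.42 (SE 0.70) and the Wnt receptor gene Fzd1 by 6.41 (0.87) on the log2 scale. Gcsam, a signalling adaptor, was higher by 6.65 with an adjusted p of 0.0108, but missed the threshold without CD8α- replicate 1 (5.64, adjusted p 0.0926), CD8α+ replicate 1 (6.91, 0.0599) or CD8α+ replicate 2 (6.40, 0.0838).

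The genes that were lower in wild type CD8α+ cells included receptors and matrix proteases. Ryr3, an intracellular calcium channel, fell from 12.70 ± 0.15 in CD8α- cells to 5.40 ± 0.01 in CD8α+ cells, a log2 change of -7.30 (SE 0.17, adjusted p = 3.36e-06), and the signalling receptor gene Sirpb1a by -6.74 (0.87, 0.00226). The prostaglandin E receptor gene Ptger3 was at least 67.1-fold lower, the inhibitory lectin gene Clec4a2 at least 51.6-fold, the macrophage elastase gene Mmp12 at least 29.0-fold, the chemokine receptor gene Ccr6 at least 27.7-fold and the lipid transporter gene Abca9 at least 13-fold. Tbx21, which encodes the transcription factor T-bet, was at least 14.2-fold lower, Lysmd2 at least 21-fold, the interferon-induced chaperone gene Rtp4 at least 21.4-fold and the killer lectin gene Klrb1f at least 11.4-fold. Mmp9, which encodes a gelatinase, was at least 11.2-fold lower (adjusted p = 0.00538), but missed the threshold without CD8α- replicate 1 (-4.80, 0.0597).

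Genes with known roles in the 2 lineages went the same ways. Of 18 textbook CD8α+ dendritic cell markers tested in wild type, 14 were higher, 0 lower and 4 not called (16 higher when adjusted over the list alone; camera adjusted p = 9.87e-13, but adjusted p = 0.247 with an estimated correlation). Among them, the RNA sensor Tlr3 rose by 4.36 (SE 0.37), the scavenger receptor Cd36 by 5.94 (0.39), the integrin Itgae by 5.67 (0.32), the lineage factor Irf8 by 3.79 (0.56) and the vesicle gene Rab7b by 5.69 (0.68), while the chemokine receptor Xcr1 was at least 8.26-fold higher. The lectin Cd207, from the C-type lectin list and not among these markers, was at least 12.5-fold higher. Batf3, a factor this lineage needs, had a difference of 0.49 (adjusted p = 0.123) and was not called. Of 15 CD8α- markers, 0 were higher, 11 lower and 4 not called (12 lower when adjusted over the list alone; camera adjusted p = 1.67e-09, but adjusted p = 0.0589 with an estimated correlation). The phagocytosis checkpoint gene Sirpa changed by -4.56 (0.33), the transcription factor gene Irf4 by -2.51 (0.22), the Notch target Dtx1 by -4.89 (0.20), the calcium-binding gene S100a4 by -3.48 (0.24) and the lymphotoxin gene Ltb by -2.76 (0.24). Conventional dendritic cell markers shared by both subsets gave 1 higher, 1 lower and 8 not called of 10, and plasmacytoid markers 1 higher and 8 not called of 9, with no camera call for either list.

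**Figure D1:**
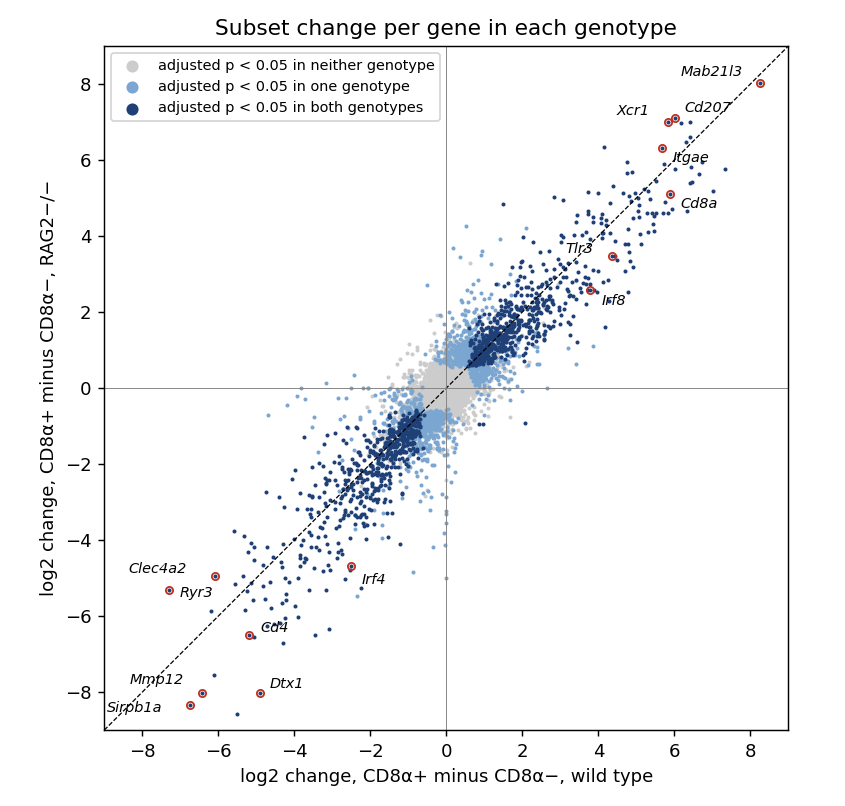
Log2 change from CD8α- to CD8α+ cells of each tested gene in wild type (horizontal axis) and in the knockout (vertical axis), with some of the named genes labelled. The changes correlated across 8763 genes at r = 0.866, and Mab21l3 lies near the upper right corner.

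Of 19 genes of MHC class I presentation and cross-presentation, 6 were higher in wild type CD8α+ cells, 1 lower and 12 not called (9 and 1 when adjusted over the list alone; camera adjusted p = 0.00587, but adjusted p = 0.523 with an estimated correlation and 0.0929 with each probe set on its own). The peptide transporter gene Tap2 rose by 1.28 (SE 0.21) and the immunoproteasome gene Psmb9 by 1.03 (0.17). Without CD8α- replicate 1 these were 1.24 (adjusted p 0.0522) and 0.99 (0.0572). The class I gene H2-K1 was at -0.03 (0.20) and its light chain B2m at -0.07 (0.16). Of 19 MHC class II presentation genes 1 was higher, 3 were lower and 15 were not called, without a camera call. H2-Aa (-0.05, SE 0.22) and H2-Ab1 (0.05, SE 0.19), the classical class II chains, differed by less than their errors, while the less common H2-Eb2 changed by -2.45 (0.34) and the peptide-loading gene H2-DMb2 by -2.31 (0.21). Cd1d1, which presents lipids, rose by 1.09 (0.16). Costimulation and maturation genes went both ways (4 higher, 5 lower and 7 not called of 16, no camera call). The costimulatory ligand gene Cd86 rose by 2.07 (0.21), the cytokine gene Il15 by 2.72 (0.34) and the chemokine gene Ccl22 by 4.07 (0.43), Il12b was at least 19.1-fold higher, and the inhibitory ligand gene Cd274 changed by -2.36 (0.17).

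Of 18 type I interferon-stimulated genes, 1 was higher in wild type CD8α+ cells, 11 were lower and 6 were not called (2 and 12 when adjusted over the list alone; camera adjusted p = 0.000161, but adjusted p = 0.284 with an estimated correlation). Ifit3, which binds viral RNA, was at least 17.2-fold lower, the oligoadenylate synthetase family genes Oasl2 and Oas2 at least 16.6-fold and 13-fold, and the antiviral gene Rsad2 changed by -2.71 (SE 0.28). NF-kB targets gave 0 higher, 3 lower and 11 not called of 14 (4 lower when adjusted over the list alone; camera adjusted p = 0.00587, but adjusted p = 0.247 with an estimated correlation), with Nfkbiz at -1.88 (0.25). Toll-like receptors and adaptors gave 3 higher and 3 lower of 15, without a camera call. The lipopeptide receptor gene Tlr1 changed by -3.24 (0.24) and the RNA receptor gene Tlr7 was at least 13.4-fold lower. C-type lectins and phagocytic receptors were 5 higher, 5 lower and 6 not called of 16, without a camera call, and included Clec4a3 at -4.82 (0.29) and the inhibitory Fc receptor gene Fcgr2b at 2.08 (0.25). Unfolded protein response genes gave 2 higher, 0 lower and 13 not called of 15 (6 higher when adjusted over the list alone; camera adjusted p = 0.0138, but adjusted p = 0.684 with an estimated correlation and 0.0801 by fry). Clock genes gave 0 higher, 3 lower and 6 not called of 9 (4 lower when adjusted over the list alone; camera adjusted p = 0.0138, but adjusted p = 0.247 with an estimated correlation), with Bhlhe40 at -2.74 (0.22) and Dbp at -2.34 (0.21). Interferon-gamma-inducible genes were 4 higher and 4 lower of 14, among them the chemokine gene Cxcl9, which rose by 4.81 (0.34), and that list had no camera call, with a median of -0.18 but a mean of 0.24.

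By limma, 1499 of the 8763 genes tested passed an adjusted p of 0.05 between the wild type subsets, 809 higher and 690 lower in CD8α+ cells. At an unadjusted p under 0.05 there were 2606. The count was 755 without CD8α- replicate 1, 803 without CD8α- replicate 2 and 811 without CD8α+ replicate 2. With 2 arrays per group the number of arrays limits the precision. In simulated data with 200 changed genes, planted log2 changes of 1 were recovered for 40% of genes, and changes of 2 for 94%. Far more genes were called in the data, where the p-value cutoff is thus less strict. These rates therefore do not describe the sensitivity of the comparison.

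In the knockout the subsets differed in much the same genes. Mab21l3 stood at 10.25 ± 0.04 in CD8α+ cells and 2.23 ± 0.00 in CD8α- cells, at least 38.0-fold higher (limma, adjusted p = 2.76e-06). Cd207 was at least 21.5-fold higher (3.40e-05), Xcr1 at least 33.0-fold (0.000708), the Wnt regulator Dkk3 at least 21.2-fold (6.29e-06), Gm36723 at least 54.4-fold (0.000360), Cltrn at least 25.7-fold, Ttc39a at least 39.0-fold, Fam149a at least 26.5-fold, the adhesion receptor gene Adgrf5 at least 12.1-fold and the lysosomal sorting receptor gene Igf2r at least 13.7-fold. Itgae rose by 6.32 (SE 0.32) and the membrane protein gene Itm2a by 5.94 (0.80), or 2.34 on its other probe set. In the other direction, Abca9 stood at 3.53 ± 0.38 in CD8α+ cells and 12.11 ± 0.08 in CD8α- cells, at least 138-fold lower (2.57e-05). Sirpb1a was at least 129-fold lower, Dtx1 at least 122-fold, Mmp12 at least 92.3-fold, Ptger3 at least 78.5-fold, Cdcp1 and Scel at least 27.5-fold and 13.5-fold, Cd4 at least 49.1-fold and the lipid transporter gene Spns3 at least 26.8-fold. Nxpe4 changed by -6.56 (0.66), Bex6 by -6.21 (0.40) and the lactate transporter chaperone gene Emb by -6.32 (0.80), with the smallest of its 3 probe sets at -1.73.

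The lineage lists went in the same directions as in wild type. Of the 18 CD8α+ markers 16 were higher in knockout CD8α+ cells, 0 lower and 2 not called (camera adjusted p = 4.78e-11, but adjusted p = 0.207 with an estimated correlation). Of the 15 CD8α- markers 0 were higher, 13 lower and 2 not called (14 lower when adjusted over the list alone; camera adjusted p = 3.14e-12), and this call held with an estimated correlation (adjusted p = 0.0343). Their median was -4.36, against -2.51 in wild type. Irf4 changed by -4.69 (SE 0.22), Sirpa by -4.44 (0.33) and Ltb by -4.36 (0.24), and Tlr3 rose by 3.46 (0.37). MHC class I presentation genes were 5 higher, 1 lower and 13 not called (9 and 1 when adjusted over the list alone; camera adjusted p = 0.0367, but adjusted p = 0.487 with an estimated correlation), with Tap2 at 1.41 (0.21) and Psmb9 at 1.39 (0.17). This list call was lost without knockout CD8α- replicate 1 or CD8α+ replicate 2, and with each probe set on its own (adjusted p = 0.124). MHC class II genes were 1 higher, 4 lower and 14 not called, without a camera call. Cd86 rose by 2.16 (0.21) and Il12b was at least 30.5-fold higher. Type I interferon-stimulated genes were 0 higher, 10 lower and 8 not called (2 and 12 when adjusted over the list alone; camera adjusted p = 0.000395, but adjusted p = 0.207 with an estimated correlation), with Oas2 at -5.66 (0.35), Rtp4 at -5.14 (0.49) and Ifit3 at -4.53 (0.41).

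C-type lectins and phagocytic receptors were 4 higher, 10 lower and 2 not called of 16 in knockout CD8α+ cells (4 and 11 when adjusted over the list alone; camera adjusted p = 0.00424, but adjusted p = 0.207 with an estimated correlation and 0.0851 with each probe set on its own). The pathogen lectin genes Cd209a and Clec7a changed by -4.78 (SE 0.43) and -3.91 (0.37), and the Fc receptor gene Fcgr3 by -3.20 (0.21). NF-kB targets gave 1 higher, 6 lower and 7 not called (1 and 9 when adjusted over the list alone; camera adjusted p = 0.00119, but adjusted p = 0.207 with an estimated correlation), with Nfkbiz at -2.92 (0.25). Notch and lymphotoxin pathway genes gave 0 higher, 4 lower and 6 not called of 10 (camera adjusted p = 0.0214, but adjusted p = 0.207 with an estimated correlation and 0.135 with each probe set on its own), among them Tnfsf14, a lymphotoxin family ligand, at least 2.58-fold lower. Splenic macrophage markers gave 0 higher, 3 lower and 9 not called of 12 (5 lower when adjusted over the list alone; camera adjusted p = 0.00240, but adjusted p = 0.457 with an estimated correlation), led by Adgre1, which encodes F4/80, at -3.13 (0.19). Without CD8α+ replicate 2 that list's call was lost. Oxidative phosphorylation was 1 higher and 22 not called of 23 (camera adjusted p = 0.00266, but adjusted p = 0.207 with an estimated correlation). Clock (4 lower of 9), cholesterol synthesis (3 higher of 14) and NK cell lists (3 lower of 7) had camera adjusted p values of 0.0367, 0.0325 and 0.0415, and 0.207, 0.608 and 0.469 with an estimated correlation. By fry the cholesterol list had no call (adjusted p = 0.156). Each of these 3 calls was lost without CD8α+ replicate 2 and at least 1 other array. Toll-like receptor genes were 3 higher and 6 lower, with Tlr1 at -4.80 (0.24), and had no camera call.

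By limma, 1909 genes passed between the knockout subsets, 973 higher and 936 lower in CD8α+ cells, and 3059 at an unadjusted p under 0.05. The count was 1177 without CD8α- replicate 1, 1168 without CD8α+ replicate 1 and 1254 without CD8α+ replicate 2. Of the genes called in either genotype, 606 were higher and 550 lower in CD8α+ cells in both and 3 were called in opposite directions. Independent calls would give 89.8 and 73.7 shared genes. The calls are not independent, however, since both use the same variance estimate of each gene. The changes in the 2 genotypes came from separate arrays and correlated across genes at r = 0.866 and rho = 0.758. Where a called gene had another probe set, that probe set changed in the same direction for 95.8% of genes in wild type and 94.1% in the knockout.

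The genotypes differed in the transcripts of the missing lymphocytes, in both subsets. Jchain, the antibody joining chain, stood at 10.27 ± 0.40 in wild type CD8α- cells and 2.77 ± 0.76 in knockout CD8α- cells, at least 38.7-fold lower (limma, adjusted p = 0.000414). Igkv8-30 was at least 34.1-fold lower in knockout CD8α- cells (0.000414) and at least 32.3-fold lower in CD8α+ cells (0.000497), and Igha at least 19.3-fold and 15.9-fold. Ms4a1, which encodes CD20, changed by -4.60 (SE 0.35) and -3.23 (0.35). The IgM receptor gene Fcmr was at least 5.51-fold and 2.92-fold lower, and the B cell coactivator gene Pou2af1 at least 2.83-fold and 2.37-fold. Of 10 B cell markers tested, 6 were lower, 1 was higher and 3 were not called in either subset (camera adjusted p = 0.00583 and 0.00959, but adjusted p = 0.538 and 0.577 with an estimated correlation). Without the filter on dim probe sets the list call was lost in both subsets (adjusted p = 0.295 and 0.481). The exception was Bank1, a B cell adaptor gene, at 2.11 (0.29) and 1.93 (0.29). Of the T cell list 4 genes were bright enough to test, 1 lower in knockout CD8α- cells and 3 in CD8α+ cells. The T cell receptor gene Trbv1 was at least 13.2-fold lower in knockout CD8α+ cells (adjusted p = 0.0105), but missed the threshold without wild type replicate 1 (-4.73, 0.0609), wild type replicate 2 (-4.59, 0.0576) or knockout replicate 2 (-3.99, 0.0627).

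Macrophage marker genes were higher in the knockout. Cd14, the lipopolysaccharide coreceptor, stood at 9.82 ± 0.80 in knockout CD8α- cells and 2.27 ± 0.15 in wild type, at least 28.2-fold higher (adjusted p = 0.000111), and was at least 11.3-fold higher in CD8α+ cells (0.000250). The complement genes C1qa and C1qc were at least 24.3-fold and 8.81-fold higher in CD8α- cells, and 14.5-fold and 2.91-fold or more in CD8α+ cells. The haemoglobin scavenger receptor gene Cd163 was at least 7.52-fold and 3.38-fold higher. The mannose receptor gene Mrc1 rose by 3.99 (SE 0.41) and 3.33 (0.41), the iron exporter gene Slc40a1 by 3.67 (0.30) and 2.93 (0.30), and the growth factor receptor gene Csf1r by 2.81 (0.20) and 2.72 (0.20). Cd14 and Csf1r are not in the macrophage list but in the Toll-like receptor and the CD8α- marker list. Of 12 splenic macrophage markers all 12 were higher in CD8α- cells (camera adjusted p = 5.64e-06, but adjusted p = 0.503 with an estimated correlation). In CD8α+ cells 10 were higher and 2 not called (11 higher when adjusted over the list alone; camera adjusted p = 5.20e-05, but adjusted p = 0.577 with an estimated correlation). Their median change was 3.83 and 2.91, or 2.45 and 1.74 with values below 5 set to 5. Of the 16 markers on the array 9 were below 5 on each wild type array, so some of the 12 passed the filter only through the knockout arrays. Of all 8763 genes tested, 2048 and 1821 were called higher in CD8α- and CD8α+ cells. C-type lectins and phagocytic receptors were 13 higher, 0 lower and 3 not called of 16 in CD8α- cells (14 higher when adjusted over the list alone; camera adjusted p = 5.71e-05, but adjusted p = 0.212 with an estimated correlation) and 7 higher and 9 not called in CD8α+ cells (8 higher when adjusted over the list alone; 0.00959, but adjusted p = 0.577 with an estimated correlation). The call in CD8α+ cells was lost with each array centred on its median (adjusted p = 0.0662) and with values below 5 set to 5 (0.0518). With those values set to 5 the list medians were 1.80 and 0.48, against 2.93 and 1.29. Clec7a rose by 2.62 (0.37) and Fcgr2b by 3.24 (0.25) in CD8α- cells, against 0.25 (0.37) and 0.24 (0.25) in CD8α+ cells.

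Other genes named for a large rise in the knockout were the interferon-induced gene Ifi44l, at least 31.4-fold in CD8α- cells and 15.6-fold in CD8α+ cells, the collagen gene Col14a1, at least 10.9-fold and 7.73-fold, the lectin gene Clec1b, at least 12.8-fold and 8.45-fold, and the scavenger receptor gene Stab2, at least 8.41-fold and 9.58-fold. The protease inhibitor gene Slpi rose by 5.15 (SE 0.50) and 4.95 (0.50). In CD8α- cells the lectin gene Cd209b was at least 4.65-fold higher, Fcgr3 at least 14.7-fold, the apoptotic cell receptor gene Axl at least 3.67-fold and the death receptor gene Tnfrsf21 at least 5.39-fold (0.60 on its other probe set). In CD8α+ cells the receptor gene Pilrb1 was at least 12.6-fold higher, Nrip2 at least 8.74-fold and Pianp at least 7.62-fold, and the import receptor gene Ipo13 rose by 4.06 (0.46). Those named for a large fall in CD8α- cells besides antibody genes were Cpe, a prohormone processing enzyme, at least 12.4-fold, 2610528A11Rik at least 8.12-fold, Igsf3 at least 5.02-fold, H3f3b at least 11.6-fold, Lad1 at least 14.8-fold, Tmem158 at least 11.3-fold and the Wnt regulator Dkk2 at least 7.91-fold, with the cell cycle inhibitor gene Cdkn2b at -4.54 (0.40). In CD8α+ cells they were the Notch ligand gene Jag1, at least 7.92-fold, Crispld2 at least 9.46-fold, Rasal2 at least 5.0-fold (-0.26 on its other probe set), 2700099C18Rik at least 5.22-fold, Dgkk at least 2.24-fold and the condensin gene Ncapg at least 12-fold, with the decoy chemokine receptor gene Ackr4 at -3.96 (0.66) and the transcription factor gene Insm1 at -3.84 (0.21).

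Those antigen-presentation genes that were called between the genotypes were mostly higher in the knockout. Of 19 MHC class II presentation genes, 11 were higher, 1 lower and 7 not called in CD8α- cells (camera adjusted p = 0.0106, but adjusted p = 0.538 with an estimated correlation). In CD8α+ cells 10 were higher, 1 lower and 8 not called (11 and 2 when adjusted over the list alone; camera adjusted p = 0.0490, but adjusted p = 0.577 with an estimated correlation). The call in CD8α+ cells was lost in turn without 6 of the 8 arrays. The invariant chain gene Cd74 rose by 1.17 (SE 0.17) in CD8α- cells, and the class II master regulator Ciita by 0.90 (0.17) and by 1.08 (0.17) in CD8α+ cells, although another of its probe sets was at 0.05 in the former and 1 at -0.36 in the latter. Cd74 was also higher in CD8α+ cells, by 0.76 (0.17), but missed the threshold without wild type replicate 1 (0.73, adjusted p 0.0672) or knockout replicate 2 (0.68, 0.0643). H2-Aa (0.52 and 0.29) and H2-Ab1 (0.32 and 0.08) were not called in either subset. Cd1d1 changed by -1.27 (0.16) and -1.34 (0.16), against the rest of the list, and its other probe set was at 0.19 and -0.36. Of 19 MHC class I presentation genes 8 were higher and 11 not called in CD8α- cells (camera adjusted p = 0.0469, but adjusted p = 0.538 with an estimated correlation), and 7 were higher and 1 lower in CD8α+ cells, without a camera call. H2-K1 rose by 1.77 (0.20) and 1.56 (0.20), while B2m, at -0.03 (0.16) and -0.15 (0.16), was not called. Costimulation and maturation genes were 1 higher, 4 lower and 11 not called in CD8α- cells (0 and 4 when adjusted over the list alone; camera adjusted p = 0.0469, but adjusted p = 0.538 with an estimated correlation), and 1 higher and 4 lower in CD8α+ cells, without a camera call. Fscn1, the actin-bundling maturation marker, changed by -2.81 (0.18) and -2.25 (0.18).

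Of 23 cell cycle genes 16 were lower, 0 higher and 7 not called in knockout CD8α- cells (18 lower when adjusted over the list alone; camera adjusted p = 2.12e-07, but adjusted p = 0.538 with an estimated correlation), and 10 were lower, 0 higher and 13 not called in CD8α+ cells (12 lower when adjusted over the list alone; camera adjusted p = 1.33e-05, but adjusted p = 0.577 with an estimated correlation). Without the filter on dim probe sets the call in CD8α+ cells was lost (adjusted p = 0.122). The proliferation marker gene Mki67 changed by -1.78 (SE 0.23) and -1.76 (0.23) and the mitotic kinase gene Aurkb by -2.29 (0.26) and -2.30 (0.26). Tyms, which makes thymidylate, was at least 3.45-fold and 2.26-fold lower, while the replication clamp gene Pcna was at -0.22 (0.25) and -0.02 (0.25). Type I interferon-stimulated genes were 7 higher, 0 lower and 11 not called in CD8α- cells (camera adjusted p = 0.0469, but adjusted p = 0.538 with an estimated correlation) and 5 higher, 0 lower and 13 not called in CD8α+ cells (0.0475, but adjusted p = 0.577 with an estimated correlation). The interferon regulator gene Irf7 rose by 3.32 (0.46) and 3.44 (0.46), and Rsad2 by 2.02 (0.28) and 3.36 (0.28). In CD8α- cells the conventional dendritic cell (5 higher of 10), Toll-like receptor (7 higher of 15), cholesterol synthesis (5 lower of 14) and clock lists (1 higher and 4 lower of 9, with Bhlhe40 at -2.21, SE 0.22) also had a camera adjusted p of 0.0469, and 0.538, 0.503, 0.680 and 0.503 with an estimated correlation. By fry the cholesterol list had no call there either (0.205). All 7 lists with a camera adjusted p of 0.0469, the MHC class I and costimulation lists included, lost the call without wild type CD8α- replicate 2 (adjusted p from 0.0624 to 0.0884), and 6 of them also without another array. The call of interferon-stimulated genes in CD8α+ cells was lost without either wild type CD8α- array (0.0560) or CD8α+ replicate 1 of wild type (0.0576) or knockout (0.108).

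**Figure D2:**
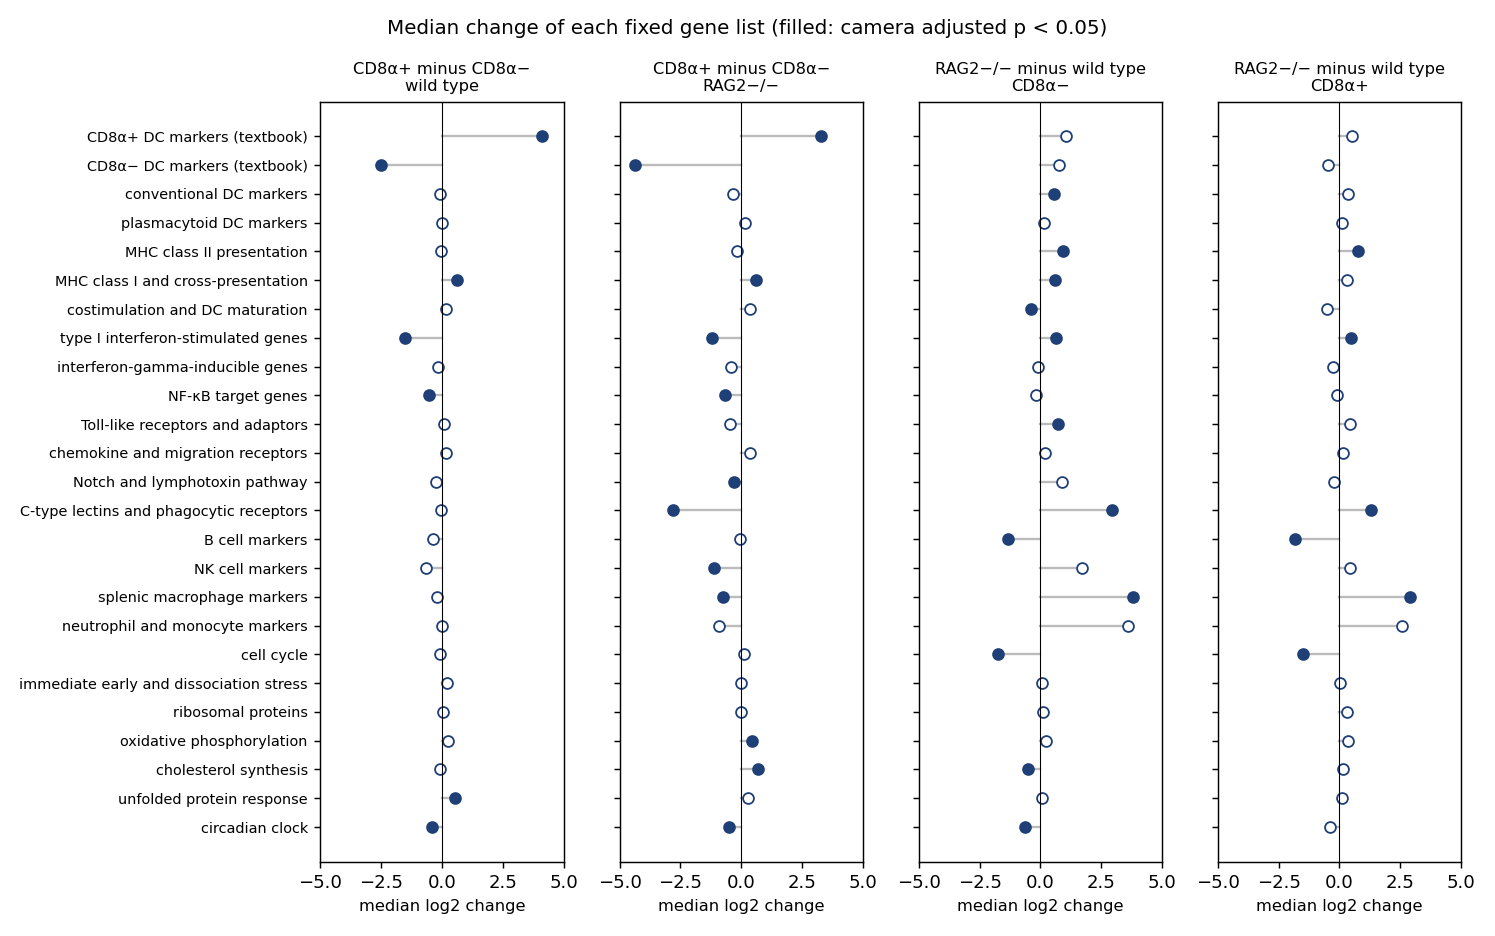
Median log2 change of each fixed gene list in the subset and genotype comparisons, on a common log2 axis. Splenic macrophage markers lie at 3.83 and 2.91 and cell cycle genes at -1.73 and -1.48 in the genotype comparisons of CD8α- and CD8α+ cells.

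The remaining lists gave no camera call between the genotypes in either subset. In CD8α- and CD8α+ cells, CD8α+ markers were 7 and 2 higher with 1 and 1 lower, CD8α- markers 6 and 4 higher with 2 and 5 lower, plasmacytoid markers 1 and 1 higher, and interferon-gamma-inducible genes 4 and 4 higher with 3 and 5 lower. NF-kB targets were 3 and 1 higher with 2 and 2 lower, chemokine receptors 3 and 1 higher with 1 and 1 lower, Notch and lymphotoxin genes 4 and 3 higher with 2 and 2 lower, and NK cell markers 3 and 2 higher with 1 and 1 lower. Neutrophil and monocyte markers were 1 and 0 higher, immediate early genes 5 and 4 higher with 4 and 3 lower, and unfolded protein response genes 3 and 2 higher with 1 and 2 lower. Erythroid, megakaryocyte and mast cell lists had 3, 3 and 1 genes bright enough to test, with 0, 1 and 0 called in CD8α- cells and the same numbers in CD8α+ cells, and no stromal gene was bright enough. Between the subsets, the immediate early, chemokine receptor, plasmacytoid and ribosomal lists had no camera call in either genotype.

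The arrays of the genotypes were not on one scale. Knockout arrays shared a lowest value of 2.23, held by 18221 to 18897 of the 45101 probe sets on each array, and their medians averaged 2.36 and 2.35, against 3.02 and 3.03 in wild type. The RNA-quality controls differed too. The difference between the 3' and 5' probe sets of Gapdh was 4.26 ± 0.85 in wild type and 2.47 ± 0.40 in the knockout (n = 4 each, 2-sided exact permutation p = 0.0286, the smallest the design allows), that of actin 1.80 ± 0.36 and 0.945 ± 0.38 (exact permutation p = 0.0571), and the 18S rRNA level 11.8 ± 0.80 and 14.1 ± 0.51 (exact permutation p = 0.0286). Processing and genotype therefore cannot be told apart here. Within ribosomal proteins, whose members are usually held at a common level, Rpl11 changed by -1.20 (SE 0.19) and -1.22 (0.19), while Rpl27 was at 1.48 (0.16) and 1.61 (0.16) in CD8α- and CD8α+ cells, with another of its probe sets at -1.20 and -1.15. That list gave 6 higher and 3 lower of 14 in CD8α- cells and 4 higher and 4 lower in CD8α+ cells, against 0 called between the subsets of either genotype. Oxidative phosphorylation was 5 higher and 2 lower of 23 in CD8α- cells and 9 higher and 2 lower in CD8α+ cells.

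Probe sets of one gene often differed in direction between the genotypes. Among genes with more than 1 probe set, the changes of the 2 brightest correlated at r = 0.255 (0.216 to 0.293) in CD8α- cells and 0.222 (0.182 to 0.260) in CD8α+ cells, across 2275 genes bright in both, against 0.867 and 0.859 for the subset changes of wild type and knockout. The other probe set of a called gene changed in the same direction for 61.4% of 1431 genes in CD8α- cells and 59.5% of 1309 in CD8α+ cells. Both of the brightest were called in 548 genes in CD8α- cells, of which 387 went the same way and 161 opposite ways. In CD8α+ cells 337 of 505 went the same way. Other probe sets of called list members were also compared in CD8α- cells. They changed in the same direction in 5 of 6 cases for macrophage markers and 7 of 10 for cell cycle genes. The share was 8 of 9 for MHC class II, 7 of 9 for MHC class I and 6 of 6 for C-type lectins. For B cell markers it was 4 of 6, for ribosomal proteins 4 of 10 and for oxidative phosphorylation 4 of 9. NF-kB targets had 2 of 5, interferon-gamma-inducible genes 2 of 4, CD8α+ markers 13 of 16 and immediate early genes 7 of 7. Called in the opposite direction were 1 probe set each for macrophage markers, cell cycle and interferon-gamma-inducible genes, and 2 for MHC class I. Ribosomal proteins had 3 such probe sets, oxidative phosphorylation 4 and NF-kB targets 3. For B cell markers in CD8α+ cells 3 of 4 changed in the same direction, and the other was called in the opposite direction. For some named genes a probe set changed in the same direction by a much smaller amount than the value given for the gene. The smallest in CD8α- and CD8α+ cells were -2.19 and -1.32 for Igha, -1.66 and -0.40 for Ms4a1 and -1.20 and -1.02 for Fscn1, with 0.88 for H2-K1 in CD8α- cells and -1.87 for Crispld2 in CD8α+ cells. Between the wild type subsets they were -3.03 for Ryr3, -2.11 for Sirpa and -1.94 for Tlr7.

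**Figure D3:**
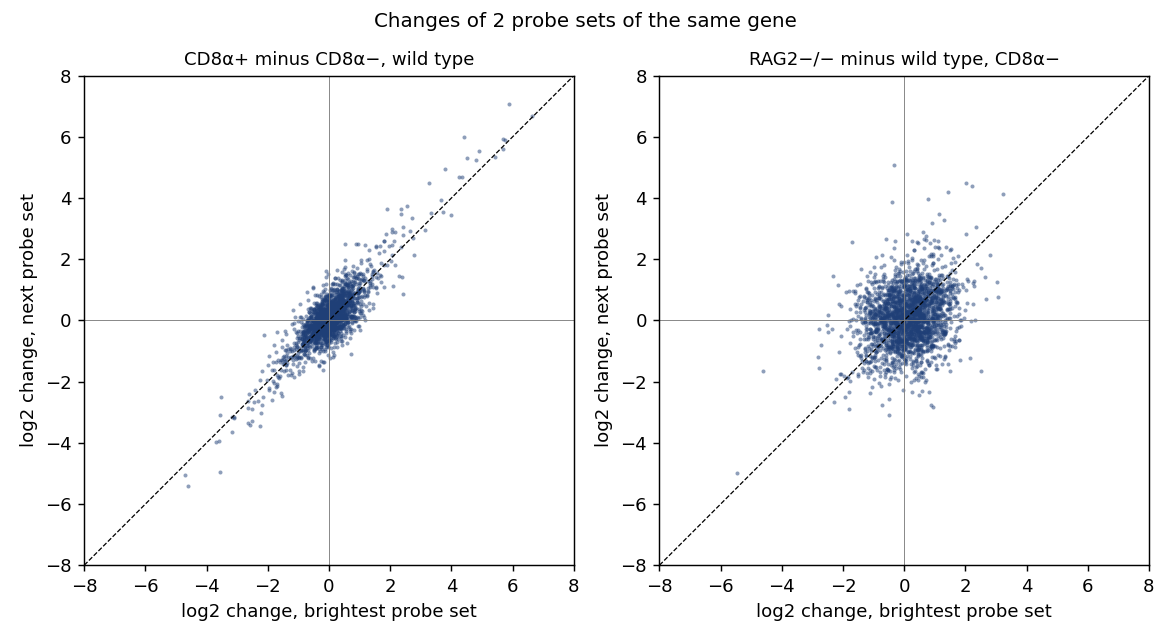
Log2 change of the brightest (horizontal axis) and the next brightest (vertical axis) probe set of each gene with more than 1, between the subsets and between the genotypes. The points follow the diagonal between the subsets of wild type cells (r = 0.867) and scatter between the genotypes in CD8α- cells (r = 0.255).

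By limma, 3548 genes passed between the genotypes in CD8α- cells, 2048 higher and 1500 lower in the knockout, and 3230 in CD8α+ cells, 1821 higher and 1409 lower. At an unadjusted p under 0.05 there were 4382 and 4229. The split depends on the processing. With each array centred on its median 4735 were higher and 542 lower in CD8α- cells, and 4590 and 476 in CD8α+ cells. Without the filter 3853 were higher and 7070 lower in CD8α- cells, and 3630 and 7048 in CD8α+ cells. In CD8α- cells 1708 passed without wild type replicate 1 and 2023 without wild type replicate 2. In CD8α+ cells 1677 and 2138 passed without wild type replicates 1 and 2, and 2102 and 2117 without knockout replicates 1 and 2. The changes in the subsets correlated across genes at r = 0.844, from separate arrays that share each genotype's processing. Of the called genes, 1420 were higher and 1071 lower in both subsets and 8 went opposite ways. The median change of all genes was 0.14 in CD8α- cells and 0.09 in CD8α+ cells. When each array was centred on its median it was 0.80 and 0.76, and 0.03 and 0.05 after quantile normalization. Relative to the median gene, the list medians in CD8α- and CD8α+ cells were 3.69 and 2.82 for macrophage markers (3.68 and 2.99 after quantile normalization), -1.87 and -1.57 for cell cycle genes (-1.80 and -1.43), -1.45 and -1.92 for B cell markers (-1.25 and -1.73), 2.79 and 1.20 for C-type lectins (2.69 and 1.34), 0.79 and 0.69 for MHC class II (0.67 and 0.66) and 0.47 and 0.24 for MHC class I genes (0.34 and 0.10). Centring moves all genes of an array alike, so it cannot alter these values.

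Transcripts of other cell types were uneven among the knockout arrays. The neutrophil genes S100a8 and Ngp stood at 10.69 and 11.65 on CD8α- replicate 2 and 9.81 and 10.18 on CD8α+ replicate 1, and at 5.19 or less on the other 6 arrays. The red cell anion exchanger gene Slc4a1 stood at 9.06 on CD8α- replicate 2 and 8.82 on CD8α+ replicate 2. The cytotoxic granule gene Gzma reached 11.53 on CD8α- replicate 2, against 9.44 on CD8α- replicate 1. The CD8α+ marker Gcsam stood at 8.49 on knockout CD8α- replicate 2 and 4.36 on replicate 1.

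**Figure D4:**
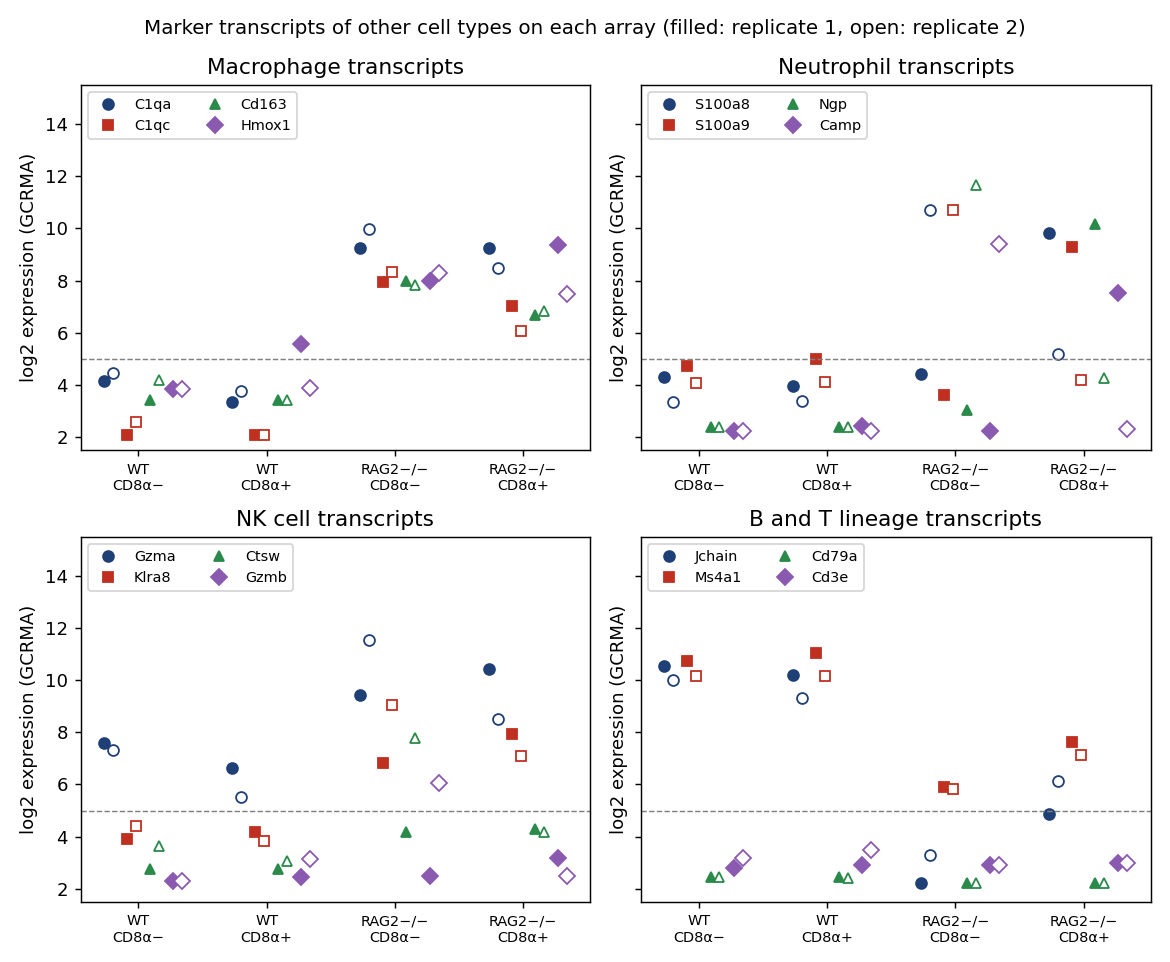
Log2 expression of marker genes of other cell types on each of the 8 arrays, one point per array. The neutrophil genes S100a8 and Ngp lie above 9 on knockout CD8α- replicate 2 and knockout CD8α+ replicate 1.

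Few genes were called as differing between the genotypes by unlike amounts in the 2 subsets. In all 21 genes passed by limma, 7 with a positive and 14 with a negative interaction, and 635 at an unadjusted p under 0.05. With values below 5 set to 5 there were 29, 19 positive and 10 negative, and after quantile normalization 20, 10 of each sign, so the balance of signs among the genes that pass depends on the processing. Of the 21, 20 had at least 1 group below 5 on each of its arrays, so the size of their interaction rests in part on background values. With low values set to 5, 12 of the 21 kept the call and 9 did not. Fcgr2b, the gene without such a group, had an interaction of -3.0 (SE 0.35, adjusted p = 0.0419). Cd209b, a lectin of marginal zone macrophages, was at least 4.65-fold higher in knockout CD8α- cells and below 5 in the other 3 groups, with an interaction of -2.22 with values set to 5 (adjusted p = 0.0165). The Notch target Dtx1 was at least 5.13-fold lower in knockout CD8α+ cells and at -0.31 (0.20) in CD8α- cells, and its interaction was -2.05 with values set to 5 (0.0397). So treated, Fcgr3 had -3.20 (0.0136), Col17a1 1.91 (0.0220), Cpe 3.59 (0.00377) and Ryr3 3.76 (0.00377), while the Notch ligand gene Jag1 was not called (-1.67, 0.292). Without any 1 wild type array, or either knockout CD8α+ array, Cd209b alone passed. Without knockout CD8α- replicates 1 and 2 the counts were 23 and 32. In simulated data with 200 changed genes, planted interactions of log2 1 were recovered for 4% of genes and of log2 2 for 70%. Fewer genes were called in the data than were recovered there, so the p-value cutoff was stricter. These rates may thus overstate the sensitivity, and genes that were not called may still differ.

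Of the lists, CD8α- markers had a negative interaction (0 higher, 1 lower and 14 not called of 15; 6 lower when adjusted over the list alone; camera adjusted p = 1.36e-06, but adjusted p = 0.109 with an estimated correlation). Notch and lymphotoxin genes (1 lower of 10; 4 lower when adjusted over the list alone; 0.000832, but adjusted p = 0.136 with an estimated correlation) and C-type lectins (2 lower of 16; 1 higher and 6 lower when adjusted over the list alone; 0.000471, but adjusted p = 0.136 with an estimated correlation) went the same way, as did Toll-like receptors (0 called of 15; 0.0271, but adjusted p = 0.257 with an estimated correlation). These lists share members with the CD8α- list. Dtx1, Notch2 and Ltb also stand in the Notch list, Cd209a and Clec12a among the lectins, and Tlr5 and Tlr7 among the Toll-like receptors. Dtx1 was the called gene of both the CD8α- and the Notch list, so the calls of those lists are not separate results. The called lectin genes, Fcgr2b and Fcgr3, are not in the CD8α- list. No list was tested without its shared members. Irf4 had an interaction of -2.18 (SE 0.31, adjusted p = 0.0593). Cholesterol synthesis genes had a positive interaction (0 called of 14; camera adjusted p = 0.000832, but adjusted p = 0.525 with an estimated correlation and 0.594 by fry), which was lost without knockout CD8α+ replicate 2 (adjusted p = 0.128). The Toll-like receptor call was lost without wild type CD8α- replicate 2, either wild type CD8α+ array or knockout CD8α+ replicate 2. The 20 other lists tested, MHC class I and class II among them, had no interaction call, and in both MHC lists 0 of 19 genes passed.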

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

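The interaction tests given here were chosen before the data were examined, while setting values below 5 to 5 and the look at probe sets without a single gene name were chosen after. Genes and lists appear because the genotype change differed between CD8α+ and CD8α- cells by limma's or camera's test of that difference.

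The genotype change was higher in CD8α+ than in CD8α- cells by 3.76 for Col17a1, 3.72 for 2610528A11Rik, 3.43 for Cpe, 3.37 for Pianp, 2.20 for the collagen receptor gene Mrc2, 1.98 for Ryr3 and 1.82 for the adhesion gene Cadm3 on the log2 scale. It was lower by the signed amounts of -4.97 for Cd209b, -3.95 for Jag1, -3.84 for the fatty acid enzyme gene Hacd4, -3.54 for the interleukin 18 receptor gene Il18rap, -3.14 for Dtx1, -3.04 for Spns3, -3.0 for Fcgr2b, -2.87 for Cd209c, -2.79 for Fcgr3, -2.67 for the nucleoside transporter gene Slc29a1, -2.64 for Dgkk, -2.54 for Gng12, -2.47 for Emilin2 and -2.16 for Cd300ld. These amounts rest in part on background values, since 20 of the 21 genes had at least 1 group below 5 on each of its arrays, Fcgr2b being the other. The other probe set of Gng12 had an interaction of only -0.19. With values below 5 set to 5, the calls of Cd209c, Dgkk, Emilin2, Gng12, Il18rap, Jag1, Mrc2, Slc29a1 and Spns3 were lost, and Cd209b had -2.22. Cd209b passed in each of the 8 fits without 1 array, and each of the 20 other genes failed in some of them. No biological explanation was tested for single genes.

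Among the lists, CD8α- markers (camera adjusted p = 1.36e-06), C-type lectins (0.000471), Notch and lymphotoxin genes (0.000832) and Toll-like receptors (0.0271) had a lower genotype change in CD8α+ cells, and cholesterol synthesis genes (0.000832) a higher one. With an estimated correlation these were 0.109, 0.136, 0.136, 0.257 and 0.525. The lectin, Notch and Toll-like receptor lists share members with the CD8α- list, so their calls need not be separate results. They were not tested without the shared members. Data outside the comparisons held further differences between the subsets: of 2336 probe sets without a single gene name that passed the filter, 95 were called in the same direction in both genotypes, 41 higher and 54 lower in CD8α+ cells. No group has the 4 arrays that a test for a single deviant array needs.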

How the results depend on the processing

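The block with exchanged numbers, the fits without the 2 knockout arrays that held neutrophil transcripts, the values set to 5 and the count by 2 probe sets were chosen after the data were seen, and the other alternatives before. The cause of the changes given here was not tested, except that fewer arrays, a further threshold or more probe sets tested change a count by construction.

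Between the wild type subsets the 1499 calls stayed within 1.5 times in each refit that kept all wild type arrays, and without 1 array they ran from 755 to 1546. Between the knockout subsets 1226 passed without a filter, 818 in a fit of those arrays alone and 1226 without the arrays with neutrophil transcripts, and 1168 to 1795 without 1 array. Between the genotypes in CD8α- cells 2181 passed with a 2-fold requirement, 5497 with each probe set on its own, 10923 without a filter, where 7070 were lower, and 1708 to 3503 without 1 array. In CD8α+ cells these were 1960, 5221, 10678 (7048 lower) and 1677 to 3468. With each array centred on its median 5066 passed in CD8α+ cells, 4590 higher and 476 lower, and 5277 in CD8α- cells, 4735 higher and 542 lower. The split into higher and lower genes between the genotypes so depends on the scaling.

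The interaction count was 3 with the replicate block, 3 with the exchanged block, 8 with each probe set on its own, 11 with limma-trend, 6 without the arrays with neutrophil transcripts and 1 to 32 without 1 array. The split into 7 positive and 14 negative became 19 and 10 with values set to 5, 10 and 10 after quantile normalization, 8 and 7 with the offset and 8 and 7 without a filter. With the filter at 7 it was 6 and 11. Which genes pass, and so the balance of signs, depends on the setting, while none of the 21 genes reversed its sign. The correlation of the subset changes was 0.888 with the filter at 7, 0.819 without the arrays with neutrophil transcripts and 0.831 to 0.862 without 1 array. That of the genotype changes was 0.765 without those arrays and 0.783 to 0.838 without 1 array. Counting only genes whose 2 brightest probe sets both passed in one direction left 291, 362, 387, 337 and 0 genes in the 5 comparisons, of 3626 genes with 2.

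Some list calls were lost under settings that kept all arrays. Of the 7 lists at 0.0469 in CD8α- cells, 6 lost the call after quantile normalization (adjusted p from 0.0536 to 0.0910) and Toll-like receptors with centred arrays (0.0738). In CD8α+ cells MHC class II and interferon-stimulated genes lost it with centred arrays (0.0707 and 0.0662), with the filter at 7 (0.0545 for both), with the offset (0.0527 and 0.0622) and with values set to 5 (0.0560 and 0.0939). Without a filter the costimulation, cholesterol synthesis and clock lists in CD8α- cells gave 0.878, 0.885 and 0.632. Between the knockout subsets the NK cell list gave 0.0536 with the filter at 7 and 0.0631 with values set to 5, and the clock list 0.0586 with each probe set on its own.

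Some values changed sign. Centring each array moves all of its genes alike, so genotype changes near 0 crossed it by construction. Under it Mab21l3 (0.58), below 5 in both genotypes, and B2m (0.63) were higher in knockout CD8α- cells, and Cd209b (0.60) and B2m (0.53) in CD8α+ cells. With the mean of its probe sets Cadm3 had a genotype change of -0.31 in CD8α+ cells. Without the arrays with neutrophil transcripts the change of Ngp from knockout CD8α- to CD8α+ cells was 1.22. That fit leaves a single array in each knockout group, on which Ngp was near background. By fry, the interferon-gamma list was higher in wild type CD8α+ cells (adjusted p = 0.0312), where camera put it lower and made no call.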

Other observations

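The tests of explanations given here were chosen after the results they address were seen, while the values of list members come from the comparisons fixed before. Values of some further list members are given here, between the genotypes for Egr2, Cry1 and Klra8 and between the subsets for Fcrla. Egr2, an immediate early transcription factor gene, stood at 8.36 and 8.52 in wild type CD8α- and CD8α+ cells and 5.62 and 5.61 in the knockout, a change of -2.75 (SE 0.17) and -2.90 (0.17), or -0.79 and -1.26 on its other probe set. The clock repressor gene Cry1 changed by -1.65 (0.29) and -1.68 (0.29). Klra8, an NK cell receptor gene, stood at 7.95 ± 1.57 and 7.51 ± 0.58 in the knockout and below 5 in wild type, at least 7.72-fold and 5.70-fold higher. The Fc receptor-like gene Fcrla, counted as a B cell marker, was higher in CD8α+ than in CD8α- cells, by 4.76 (0.36) in wild type and at least 24.5-fold in the knockout, where the smallest of its 3 probe sets changed by 2.80.

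The large number of genes called between the genotypes was set against the probe sets of one gene. If nearly every call came from a change of the whole transcript, the other probe set of a called gene would change in the same direction in at least 90% of genes, as it did between the subsets. It did so for 61.4% of genes in CD8α- cells and 59.5% in CD8α+ cells, which argues against that reading. Effects on single probe sets, from separate normalization or RNA amplification, may therefore make up a large part of the calls. Genotype and processing cannot be told apart by the design, so how many of the calls are due to lymphocyte loss stays open.

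The rise of macrophage markers was set against a general shift between the arrays and against macrophages carried into the knockout sorts. The list median was 3.83 in CD8α- cells, outside the range of -0.868 to 0.945 that held 99% of 10000 random lists of like level. Genes of like level thus did not in general share a rise of that size. The list had already been called by camera, which also sets it against the other genes. The random lists ignore correlation among members, so the draw adds no separate support. Macrophages of one kind carried over would add their transcripts to CD8α- and CD8α+ cells in one ratio. For 8 of the 12 members tested the log2 ratio of the added amounts lay within 1 of the median, while Axl (2.69), Adgre1 (2.37) and Hmox1 (-0.25) lay outside it and Vcam1 gained nothing in CD8α+ cells (-0.53, SE 0.31). The 3 probe sets of Vcam1 ran from -1.76 to 3.29 in CD8α- cells. This neither excludes carried-over macrophages nor supports them as the whole source. The CD8α sort is the only gate the labels name, 9 of the 16 markers on the array were below 5 on each wild type array, 5 of the 16 also stand in the lectin list, and Slc40a1 stood at 13.45 and 12.50 in the knockout. Carry-over, a rise within the dendritic cells and separate processing stay open.

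The fall of cell cycle genes was set against a general shift and against B or T cells carried into the wild type sorts. The list median was -1.73 in CD8α- cells, outside the range of -0.372 to 0.695 that held 99% of such lists. Genes of like level thus did not in general share a fall of that size. This list too had already been called by camera, so the draw adds no separate support. Of the B cell markers bright enough to test, 6 of 10 were lower in knockout CD8α- cells, 3 were not called and Bank1 was higher. Of the T cell markers 1 of 4 was lower and 3 were not called. Levels of different probe sets cannot be set against each other, so these counts do not show whether carried-over B or T cells held enough cell cycle transcripts, and neither cell type is excluded or supported as a source. A lower rate of division of dendritic cells without lymphocytes may be the cause but was not tested, and separate processing stays open.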
